A study of Mus musculus with 12 samples.

How the data were processed

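PolyA RNA of 12 samples of mouse heart was sequenced, with 3 samples in each of 4 groups: control diet sham, control diet TAC, BCAA-free sham and BCAA-free TAC. The labels do not say whether a sample is 1 heart or a pool, or at what time of day hearts were collected. The p-values measure only the spread between these samples, which may be technical. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b, Subread 1.5.2 and DESeq2 (no version given) were used with GRCm38 and mm10; the role of each is not stated. The authors deposited 4 tables, 1 per pair of groups, each with 6 libraries, so that each library stands in 2 tables. The deposited signal of a gene in a library is a normalized read count, a gene count divided by 1 size factor per library within its table. Each value was a whole multiple of the library's smallest step, within 0.01 of a whole number of reads, and the reads of a library were the same in its 2 tables. The size factors differed between tables, so values were not compared across tables. The log2 fold changes and the p-values, raw and adjusted, come from the authors' own comparison within each table, per the file headers; they served only for a count of shared calls. The tables list 15505, 15855, 15438 and 15936 genes for TAC on the control diet, TAC on the BCAA-free diet, the diet after sham and the diet after TAC; no listed gene had a mean value under 7.25, so genes at low values are absent. Gene positions, transcript length and GC content (of the longest transcript) came from GENCODE M21 on GRCm38, matched by Ensembl ID, and 99.8% of the IDs of a table matched.

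The comparisons, tests, gene lists, named genes and most alternatives were chosen before the data were examined. Each pair of groups was compared with limma 3.58.1 in R 4.3.3 (moderated test with an intensity trend and robust variances; statmod 1.5.0) on log2 of the value plus 1, within the 6 libraries of its table, on genes with a mean value of at least 10. P-values were adjusted by Benjamini-Hochberg over all genes tested, and genes with an adjusted p under 0.05 were called. The interaction of diet and surgery was fitted in the same way on the 12 libraries of the joined TAC tables, over 15195 genes found in both. The alternative with only the 6 samples compared, chosen beforehand, is the fit itself here, because the tables were normalized separately. Depth in recovered reads was 13848953 to 52059546 per library over the genes of the tables that compare TAC with sham. Counting error was small beside the spread between replicates, with a mean chi-square per gene of 4.74 to 68 between replicates where counting error alone gives 1, so no replicates were copies of one library. TAC markers were compared by an exact two-sided permutation test of 3 against 3, whose smallest p is 0.1.

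Of 35 gene lists of cell types, pathways and stress programs, the 34 with at least 5 tested members were tested with limma's camera at its preset correlation of 0.01, two-sided, with p-values adjusted over the lists of a comparison; camera with an estimated correlation and fry were alternatives. A list's median is over its tested members, and its members are counted as called over all genes or adjusted over the list alone. No list that passed camera differed in sign between its median, its mean and its test. Where 2 numbers stand after a list, they are its median and its adjusted p by camera. Genes were named by a rule: per comparison the 6 largest rises and the 6 largest falls among called genes with a mean value of at least 100, no overlap between the groups and a symbol that is not a model or pseudogene. The rule also names up to 4 called members of a list with the smallest p, or 2 where none was called; TAC and diet genes fixed in advance; and for the interaction the 10 genes with the smallest p. Some genes that fall under the rule are not reported here.

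Alternatives were TMM-rescaled values, scaling to library totals alone, no filter, a mean value of at least 100, a pseudocount of 10, the replicate number as a block, DESeq2 1.42.0 and limma-voom on the recovered reads, an absolute log2 fold change of at least 1, and each library left out in turn. Under these normalized values the median-of-ratios alternative took the form of the TMM-rescaled values. After the data were seen, edgeR 4.0.16 quasi-likelihood on the recovered reads of 6 or 12 libraries, limma on 12 libraries and the removal of each library's trend over GC content and log2 transcript length (natural splines) were added, as were some alternatives for the size of the response, among them an average TAC effect that weights each diet by its precision, per gene or with 1 weight for all. The pipeline was tested on simulated counts with known changes, drawn from the real means and depths. For TAC on the control diet 70.7% of genes changed 2-fold and 94.8% of those changed 4-fold were recovered. The shares were 85% and 96.9% for TAC on the BCAA-free diet, 72.4% and 94.8% for the diet after sham, 80.8% and 98.9% for the diet after TAC and 51.5% and 83% for the interaction. False calls numbered 18 of 180, 16 of 194, 15 of 178, 20 of 194 and 4 of 138 calls in that order. Their share was above the one that the adjusted p threshold allows in each comparison of a pair of groups, but not in the interaction. A raised simulated list was found in each of the 5 comparisons and a random list in 0. Simulated genes were drawn independently, so this does not test camera on lists whose genes vary together. The matrix list, for example, had an estimated correlation of 0.905 for TAC on the control diet. Splice forms, sequence variants and time of collection were not analysed here.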

Results

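RNA was measured by polyA sequencing in 12 samples of heart from male C57Bl/6J mice, 12 weeks old, in 4 groups of 3 samples. The mice ate either a control diet with all essential amino acids or a diet free of branched-chain amino acids (BCAA: leucine, isoleucine and valine). The diets began 4 days before either sham surgery or transverse aortic constriction (TAC), an operation that narrows the aorta and makes the left ventricle pump against a higher pressure. Hearts were taken 2 weeks after surgery. Depth, as reads recovered from the deposited values, ranged from 13848953 in BCAA-free sham replicate 2 to 52059546 in control diet TAC replicate 3 over the genes of the tables that compare TAC with sham. Values are normalized read counts, given as mean ± SD with n = 3 per group, and log2 fold changes are given ± SE. Each comparison was made within the table that holds its libraries, because the tables had been normalized separately. Gene positions refer to GRCm38.

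The standard marker genes of cardiac pressure overload had higher values after TAC on both diets. On the control diet, Nppa, which encodes atrial natriuretic peptide, averaged 7763 ± 4456 in sham and 43959 ± 36605 in TAC hearts, a ratio of 5.66. On the BCAA-free diet Nppa averaged 8234 ± 2434 in sham and 28579 ± 12514 in TAC hearts, a ratio of 3.47. Nppa lies on chromosome 4, 148000722 to 148002079 and its neighbour Nppb on chromosome 4, 147985788 to 147987205. The TAC to sham ratio of Acta1, skeletal alpha-actin, was 6.55 on the control diet and 2.87 on the BCAA-free diet. For Myh7, the beta-myosin heavy chain of the fetal heart, it was 4.69 and 1.54, and for Nppb, brain natriuretic peptide, 2.9 and 1.76. All 3 TAC samples lay above all 3 sham samples for these 4 genes on both diets, which gives an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. Atp2a2, the calcium pump of the sarcoplasmic reticulum, had a TAC to sham ratio of 0.653 on the control diet, with no overlap (exact permutation p = 0.1), and 0.954 on the BCAA-free diet (exact permutation p = 0.7). Myh6, the adult alpha-myosin heavy chain, overlapped between sham and TAC on both diets (exact permutation p = 0.2 and 0.8). Control diet TAC replicate 2 stood apart, with a Nppa value of 86226 against 22999 and 22651 in replicates 1 and 3 of its group.

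**Figure D1:**
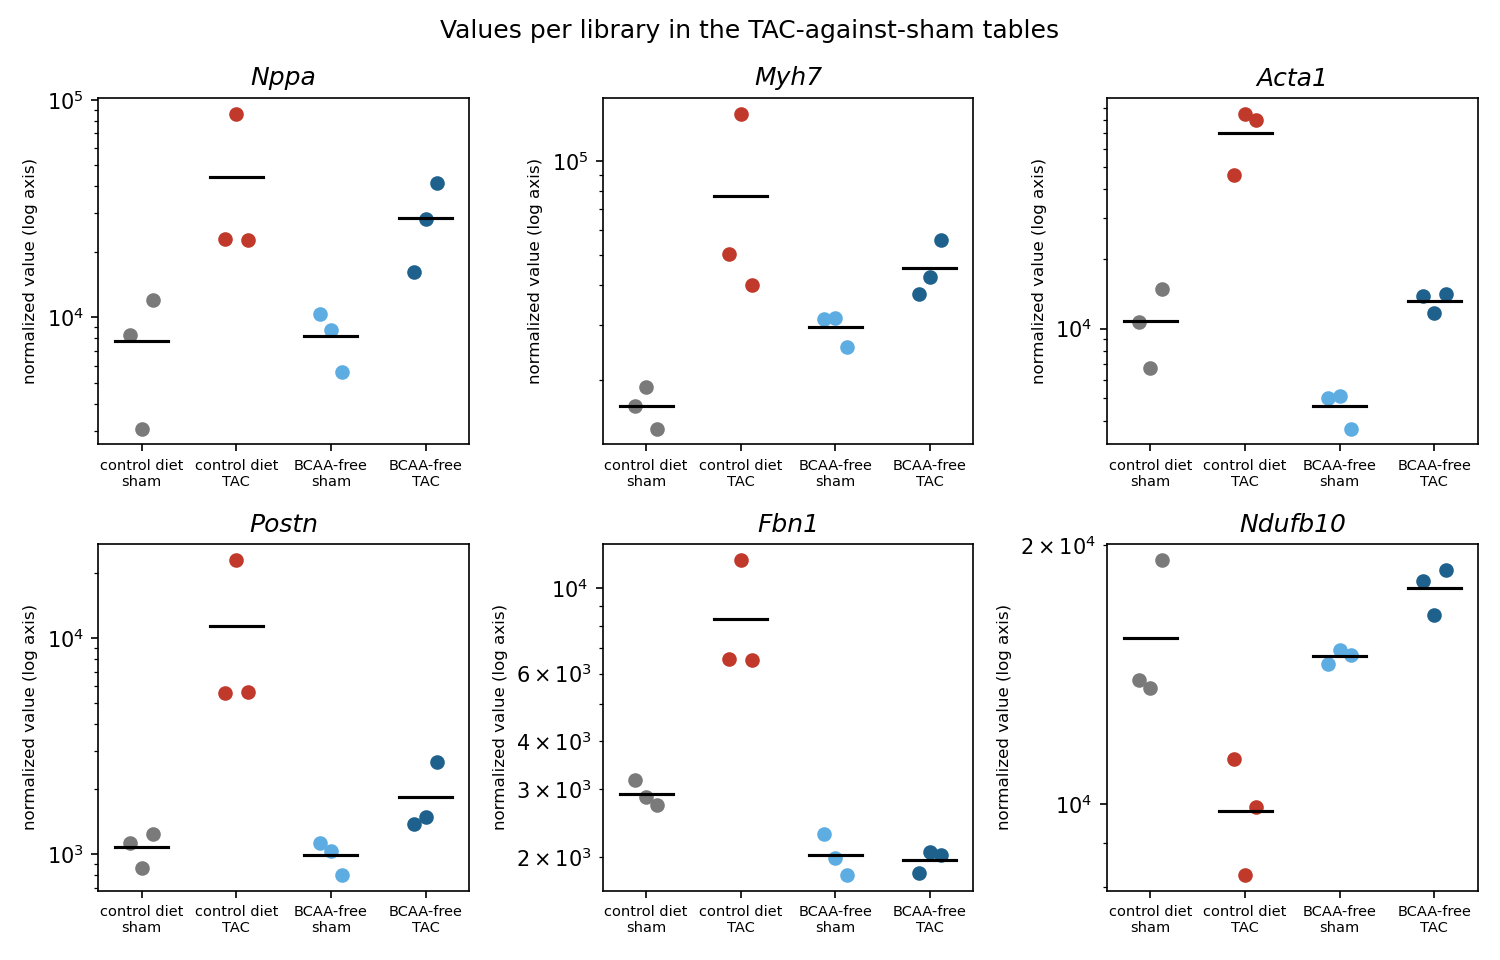
Normalized values (vertical log axes) of 6 genes in each of the 12 libraries, with 1 point per library and a black bar at each group's mean; the horizontal axis gives the group, and each diet's values come from its own TAC table. For Nppa, the control diet TAC points lie at 22999, 86226 and 22651, above the control diet sham mean of 7763.

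TAC was compared with sham on the control diet to ask how 2 weeks of pressure overload altered cardiac RNA with a normal amino acid supply. Genes of the extracellular matrix rose together: 25 of the 35 measured members of the fibrosis list rose, none fell, and the median log2 fold change was 2.00. Postn, which encodes the matricellular protein periostin, went from 1074 ± 192 to 11411 ± 10031 (3.08 ± 0.54, adjusted p = 0.0421). The collagen gene Col1a1 went from 2221 ± 661 to 12036 ± 9169 (2.23 ± 0.48, adjusted p = 0.049). Among the largest rises of annotated genes with a mean value of at least 100 and no overlap between the groups were the secreted collagen-associated protein gene Cthrc1 (4.52 ± 0.82), the thrombospondin gene Thbs4 (3.70 ± 0.60), tenascin C, Tnc (3.34 ± 0.43), Cilp (3.30 ± 0.54) and Ltbp2 (3.15 ± 0.63). Of the 15 genes of the hypertrophy and fetal program, 7 rose (median 1.07). They included Acta1 (2.73 ± 0.31), Ankrd1 (1.92 ± 0.29), Xirp2 (1.91 ± 0.31), Rcan1, a target of calcineurin signalling (0.90 ± 0.20), Nppb (1.61 ± 0.36) and Myh7 (2.01 ± 0.42). Nppa had a log2 fold change of 2.40 ± 0.67, adjusted p = 0.0793, and Atp2a2 of -0.64 ± 0.20, adjusted p = 0.0845; neither passed. The 6 largest falls of such genes were Tbc1d10c (-1.63 ± 0.28), Ybx2 (-1.42 ± 0.28), Gfra4 (-1.31 ± 0.26), Ano10 (-1.24 ± 0.16), the mitochondrial folate enzyme gene Aldh1l2 (-1.22 ± 0.25) and Phkg1 (-1.17 ± 0.23).

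Genes of fatty acid oxidation, the respiratory chain and BCAA catabolism moved the other way on the control diet. Of 32 fatty acid oxidation genes, 8 fell and none rose (median -0.57, adjusted p = 3.15e-14 by camera). Among them were Acot1 (-1.12 ± 0.25), the malonyl-CoA decarboxylase gene Mlycd (-0.73 ± 0.13), Esrra, a nuclear receptor that drives mitochondrial genes (-0.57 ± 0.12), and Cpt2 (-0.57 ± 0.13). The 40 nuclear genes of the citric acid cycle and respiratory chain had a median of -0.54 (camera adjusted p = 3.42e-16). Of these Sdhc, 1 gene, fell over all genes tested (-0.61 ± 0.13) and 39 did when adjusted over the list alone. BCAA catabolism genes had a median of -0.39 (camera adjusted p = 3.27e-08), with Mccc2 of the leucine pathway as the 1 member that fell (-0.63 ± 0.13) and 19 falling when adjusted over the list alone. Lower medians were also found for the ribosomal protein (-0.27, camera adjusted p = 5.61e-05), glycolysis (-0.24, 0.0039) and calcium handling lists (-0.28, 0.0113). In glycolysis Ldhb fell (-0.76 ± 0.16) and Pfkp rose (0.87 ± 0.20). No ribosomal protein or calcium handling gene passed on its own. The ribosomal protein median was -0.088 without control diet sham replicate 3 (camera adjusted p = 0.0775), and the calcium handling median -0.23 and -0.20 (0.0611 and 0.11) without control diet sham replicates 1 and 2. With an estimated correlation between genes none of the 6 lists that moved down kept its call. The values were adjusted p = 0.586 for fatty acid oxidation, BCAA catabolism, the respiratory chain and glycolysis, adjusted p = 0.721 for calcium handling and adjusted p = 0.755 for ribosomal proteins.

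Interferon-stimulated genes and markers of macrophages and of smooth muscle were higher after TAC on the control diet. Lymphocyte (-0.082, camera adjusted p = 0.838) and neutrophil and mast cell markers (0.23, 0.574) did not pass. Interferon-stimulated genes rose with 8 of 25 members (median 0.75, camera adjusted p = 1.32e-11), for example Ifit2 (1.03 ± 0.15), Zbp1 (1.38 ± 0.25), the RNA sensor gene Ifih1 (0.75 ± 0.13) and Gbp3 (0.71 ± 0.13). In the macrophage list 3 of 25 rose (median 0.56, 4.03e-06), namely the antigen presentation genes Cd74 (0.83 ± 0.17) and H2-Aa (0.89 ± 0.19) and the colony-stimulating factor receptor Csf1r (0.42 ± 0.092). In the list of smooth muscle and pericyte markers 3 of 12 rose (median 0.59, 1.75e-04), namely Cnn1 (1.36 ± 0.28), Tagln (0.77 ± 0.16) and Mcam (0.73 ± 0.13). Chemokine and cytokine genes had a median of 0.62 (0.00293) with 1 gene up, the osteopontin gene Spp1 (2.59 ± 0.49). The cell cycle list had a median of 1.25 (3.98e-06), with Bub1 up (2.10 ± 0.47), Cenpf down (-0.88 ± 0.17) and 16 up when adjusted over the list alone. That call was lost among genes with a mean value of at least 100 (median 0.39, adjusted p = 0.378). Fibroblast markers had a median of 0.30 with 2 of 14 up and missed the threshold (camera adjusted p = 0.0736), and endothelial markers 0.051 with 1 of 17 up (0.0836). The matrix and hypertrophy lists passed camera at adjusted p = 3.48e-25 and 5.07e-07. With an estimated correlation all 7 lists that moved up lost their call, at adjusted p = 0.586 for each.

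By limma, 622 of 15397 genes changed after TAC on the control diet, 454 up and 168 down, of which 207 and 37 by at least 1 on the log2 scale. All 622 separated the 3 libraries of one group from the 3 of the other, as 35.2% of all tested genes did against 10% by chance. The authors' deposited test called 1291 up and 916 down, including 621 of the 622. The count rested on single libraries: it was 2 without control diet sham replicate 1, 2 without replicate 2 and 98 without replicate 3 of that group. It was 1061 without control diet TAC replicate 1, 196 without replicate 2, and 0 by limma without replicate 3, where 3372 genes had an unadjusted p under 0.05. Scaling to library totals alone gave 1416 genes, 1267 up and 149 down, with the median of all genes shifted to 0.14. The other counts were 1537 (654 up and 883 down) with each library's trend over GC content and transcript length removed and 2206 by DESeq2. There were 337 by limma-voom, and 2988 by limma and 3046 by edgeR on all 12 libraries.

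The same comparison on the BCAA-free diet asked what pressure overload did without dietary BCAA. Among annotated genes with a mean value of at least 100 and no overlap, the 6 largest rises were Cebpb, which encodes a transcription factor of stress and inflammatory responses (1.62 ± 0.11, adjusted p = 5.76e-05), Acta1 (1.53 ± 0.13, adjusted p = 0.00199), Wisp2 (1.29 ± 0.25), Il17d (1.24 ± 0.22), Fam46b (1.24 ± 0.28) and Igfbp7 (1.06 ± 0.13). Cebpb, on chromosome 2, 167688915 to 167690418, went from 866 ± 67 in sham to 2671 ± 389.7 in TAC hearts. The 6 largest falls among them were the stress and immediate early genes Atf3 (-1.53 ± 0.14, adjusted p = 7.84e-04) and Fos (-1.09 ± 0.20), and Lmbrd2 (-1.17 ± 0.25), Cep85l (-1.0 ± 0.21), Atad2b (-0.95 ± 0.17) and Mid1 (-0.91 ± 0.24). Clock, a core gene of the circadian clock, fell (-0.82 ± 0.10). Of the fixed marker genes, Myh7 rose (0.61 ± 0.15, adjusted p = 0.0495). Nppa (1.74 ± 0.45, adjusted p = 0.103), Nppb (0.83 ± 0.19, adjusted p = 0.0552) and Postn (0.85 ± 0.29, adjusted p = 0.16) did not pass, nor did Col1a1 (0.73 ± 0.30, adjusted p = 0.219), Atp2a2 (-0.066 ± 0.085, adjusted p = 0.682) and Myh6 (0.04 ± 0.076, adjusted p = 0.799).

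Matrix genes rose on the BCAA-free diet as well, with 6 of 35 members up over all genes, 20 up when adjusted over the list alone and a median of 0.48. Examples were the tissue inhibitor Timp1 (0.96 ± 0.25), Sparc (0.60 ± 0.099) and Fstl1 (0.34 ± 0.092). The hypertrophy list had a median of 0.16 with 2 of 15 up, and in the macrophage list 3 of 25 rose (median 0.34), the complement genes C1qa (0.41 ± 0.10), C1qb (0.44 ± 0.12) and C1qc (0.43 ± 0.087). In the respiratory chain list 4 of 40 rose (median 0.14), namely Cox7a1 (0.50 ± 0.078), Cox8b (0.41 ± 0.076), Cox5b (0.30 ± 0.074) and Ndufb10 (0.26 ± 0.07). In the sarcomere list (median 0.11) Mybpc3 (0.36 ± 0.074), Tnnc1 (0.37 ± 0.077) and Actc1 (0.36 ± 0.095) rose while Nebl fell (-0.34 ± 0.083). These lists passed camera, at adjusted p = 4.46e-12 for matrix, 0.00501 for hypertrophy, 4.52e-04 for macrophage, 1.75e-04 for respiratory chain and 0.00812 for sarcomere genes. With an estimated correlation none did, at adjusted p = 0.85 for the respiratory chain and 0.771 for the others. Camera also passed for glycolysis (0.16), ribosomal protein (0.11), blood cell (0.18) and atrial genes (0.50) upward and for unfolded protein response (-0.13), FOXO and autophagy (-0.10) and NRF2 genes (-0.12) downward. All of these lost the call with an estimated correlation (adjusted p = 0.771 to 0.85). Without BCAA-free sham replicate 3 the median was 0.0040 for the unfolded protein response, -0.051 for NRF2, 0.29 for atrial and 0.11 for blood cell genes. Without replicate 2 of that group it was -0.066 for FOXO and 0.078 for ribosomal protein genes, and none of the 6 passed the threshold. Without BCAA-free TAC replicate 1 the unfolded protein response (-0.13), FOXO (-0.088), blood cell (0.13) and ribosomal protein calls (0.066) were lost. Without replicate 2 the NRF2 call was lost (-0.13), and with the GC content and length trends removed so were the glycolysis (0.028), ribosomal protein (0.024) and blood cell calls (0.069). The blood cell call was also lost among genes with a mean value of at least 100 (0.18, adjusted p = 0.0671). Interferon-stimulated genes (0.044, camera adjusted p = 0.424), cell cycle genes (0.056, 0.817), BCAA catabolism genes (0.016, 0.817) and fatty acid oxidation genes (0.02, 0.817) did not pass. Within the BCAA list Acadsb (-0.35 ± 0.071), Ppm1k (-0.32 ± 0.073) and Dbt (-0.27 ± 0.069) fell.

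In all, 977 of 15670 genes changed by limma, 524 up and 453 down, but only 29 and 10 by at least 1 on the log2 scale. All 977 separated the 3 libraries of one group from the 3 of the other, against 29.5% of all tested genes and 10% by chance. The called genes differed in base composition: median transcript GC content was 56.7% for genes that rose and 43.2% for genes that fell, and median transcript length 2161 and 6434 bases. The BCAA-free TAC libraries had the highest rank correlations of all 12 with GC content across genes (Spearman 0.20, 0.40 and 0.39 for each library's deviation from the mean of the 12), against -0.22 to 0.038 in the other 9. With that trend and the trend over length removed from each library, 85 genes were called, 77 up and 8 down, of which 74 were among the 977. The count was 140 without BCAA-free sham replicate 1, 108 without replicate 2 of that group, 380 without BCAA-free TAC replicate 2 and 48 without replicate 3, and on all 12 libraries 59 by limma and 62 by edgeR. Library totals alone gave 379 up and 493 down. The authors' deposited test called 755 up and 703 down, with 962 of the 977 among them.

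**Figure D2:**
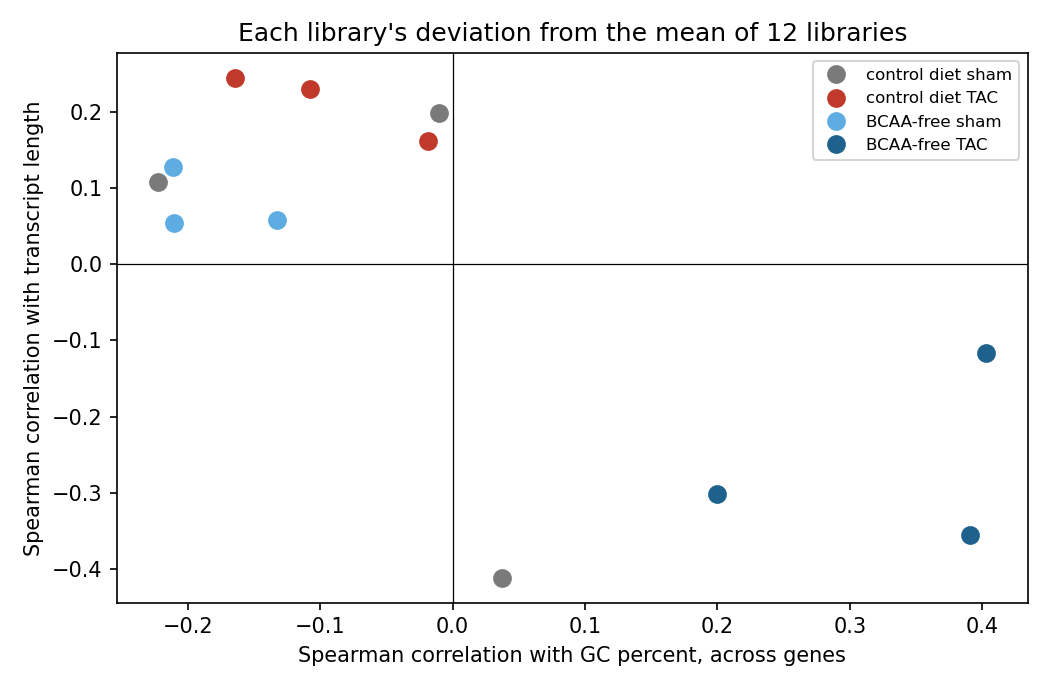
Spearman correlation across genes of each library's deviation from the mean of the 12 libraries with GC percent (horizontal axis) and with transcript length (vertical axis), 1 point per library coloured by group. The 3 BCAA-free TAC libraries lie at 0.20, 0.40 and 0.39 on the GC axis, and control diet sham replicate 3 has the lowest value on the length axis, -0.41.

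The diets were compared after sham surgery to ask what removing BCAA did without pressure overload. Few genes passed. Of the 6 largest falls among annotated genes with a mean value of at least 100 and no overlap, the top genes were Crybg3 (-1.63 ± 0.19, adjusted p = 0.0065) and Tfrc, the transferrin receptor that takes up iron (-1.52 ± 0.15, adjusted p = 0.00169). The others were Gadd45b (-1.48 ± 0.22), the kinase gene Pim1 (-1.43 ± 0.13, adjusted p = 0.00135), the collagen gene Col3a1 (-1.42 ± 0.15) and Papln (-1.32 ± 0.18). Tfrc, on chromosome 16, 32608920 to 32632794, averaged 2320 ± 555 on the control diet and 797 ± 37.5 on the BCAA-free diet. The 6 largest rises by the same choice of genes included the clock gene Per2 (2.14 ± 0.32, adjusted p = 0.0332), Tcf23 (1.70 ± 0.32) and Cdo1, cysteine dioxygenase (1.29 ± 0.18). They also included the smooth muscle genes Myh11 (1.18 ± 0.20) and Lmod1 (1.12 ± 0.19), and Fmo2 (1.08 ± 0.12). Of the genes fixed for the diet comparisons, none passed. Among the enzyme and kinase genes these were Bcat2 (0.086 ± 0.11, adjusted p = 0.725), Bckdha (0.066 ± 0.11, adjusted p = 0.807), Bckdhb (0.13 ± 0.11, adjusted p = 0.596) and Bckdk (-0.04 ± 0.097, adjusted p = 0.872). The others were Ppm1k (0.77 ± 0.18, adjusted p = 0.0803), Klf15 (0.38 ± 0.12, adjusted p = 0.169) and the asparagine synthetase gene Asns (-0.55 ± 0.26, adjusted p = 0.317). Fgf21 was not analysed here.

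Macrophage markers fell with 3 of 25 members (median -0.61, camera adjusted p = 5.48e-09; adjusted p = 0.75 with an estimated correlation). All 3 were antigen presentation genes, Cd74 (-1.0 ± 0.14), H2-Aa (-1.06 ± 0.18) and H2-Ab1 (-1.29 ± 0.21). In the matrix list 6 of 35 fell (median -0.33, 1.69e-04; 0.75 with an estimated correlation), including Col3a1, Col15a1 (-1.10 ± 0.12), Fbn1 (-0.77 ± 0.12) and Mmp2 (-0.55 ± 0.10). In the fibroblast list Pi16 fell (-0.95 ± 0.13; median -0.15, 0.00147; 0.75 with an estimated correlation). Lower medians were found for interferon-stimulated genes (-0.44, 3.53e-06), of which none passed on its own, cell cycle genes (-0.59, 4.24e-05), with Mki67 down (-1.71 ± 0.31), glycolysis genes (-0.17, 8.18e-04), with Gapdh down (-0.61 ± 0.12), and respiratory chain genes (-0.15, 2.23e-04). Adipocyte markers had a higher median (1.01, 5.51e-05) with the lipase gene Lipe up (0.58 ± 0.11). So had unfolded protein response genes (0.23, 4.24e-05) with none up on its own, smooth muscle markers (0.20, 0.00324) and glucocorticoid response genes (0.19, 0.0309), with Tsc22d3 up (0.54 ± 0.095). With an estimated correlation the 11 calls were all lost (adjusted p = 0.75 to 0.756). The cell cycle call was lost among genes with a mean value of at least 100 (median -0.085) and the respiratory chain call without control diet sham replicate 3 (median -0.034, adjusted p = 0.175). The glucocorticoid median was -0.18 without control diet sham replicate 1 and 0.12, short of the threshold, without BCAA-free sham replicate 1. The amino acid response list missed the threshold (median -0.026, camera adjusted p = 0.26), with Aldh1l2 down (-1.23 ± 0.19).

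In all, 95 of 15217 genes differed by limma, 38 up and 57 down, and all 95 separated the 3 libraries of one group from the 3 of the other, against 23% of all tested genes and 10% by chance. The count was 32, 211 and 475 without control diet sham replicates 1, 2 and 3, and 14 and 6 without BCAA-free sham replicates 1 and 2. Replicate 3 of the control diet sham group stood apart, with a Spearman correlation of -0.41 between its deviation from the mean library and transcript length, against 0.11 and 0.20 in replicates 1 and 2. The count was 375 with the GC content and length trends removed, 532 by DESeq2, 322 by edgeR on all 12 libraries and 52 among genes with a mean value of at least 100. Library totals alone gave 52 up and 45 down.

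More genes differed between the diets after TAC than in any other comparison of groups, and this comparison asks how removing BCAA altered the overloaded heart. Clock genes moved in opposite directions by arm. Dbp (2.70 ± 0.11, adjusted p = 1.22e-05), Ciart (2.24 ± 0.19), Per2 (1.85 ± 0.11) and Per3 (1.73 ± 0.11), which are expressed in one phase of the circadian cycle, rose on the BCAA-free diet. Arntl, which encodes BMAL1 and peaks in the opposite phase, fell (-2.38 ± 0.13, adjusted p = 4.90e-05). Dbp lies on chromosome 7, 45705088 to 45710203, and averaged 874 ± 106 on the control diet and 5696 ± 553 on the BCAA-free diet. In the clock list 9 of 19 genes rose and 4 fell (median 0.61, camera adjusted p = 0.00973; adjusted p = 0.691 with an estimated correlation). Of annotated genes with a mean value of at least 100 and no overlap, the other large rises were Ankrd63 (2.42 ± 0.17), Pfkfb1 (2.31 ± 0.51), Tcf23 (2.26 ± 0.27) and Cebpb (2.20 ± 0.11, adjusted p = 3.07e-05). Cebpb averaged 599 ± 28.7 on the control diet and 2770.1 ± 405 on the BCAA-free diet. The largest falls by the same choice were of the proliferation genes Top2a (-3.76 ± 0.54), Mki67 (-3.41 ± 0.47) and Iqgap3 (-3.17 ± 0.43). Next were the matrix genes Adamts4 (-3.17 ± 0.28, adjusted p = 4.34e-04), Tnc (-3.02 ± 0.73) and Cthrc1 (-2.93 ± 0.89). The Tnc call was lost without control diet TAC replicate 2 (adjusted p = 0.0717). The Cthrc1 call was lost in 8 of 18 settings (adjusted p up to 0.167), among them without control diet TAC replicate 1 and BCAA-free TAC replicates 1 and 2, with the GC content and length trends removed and by limma-voom.

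**Figure D3:**
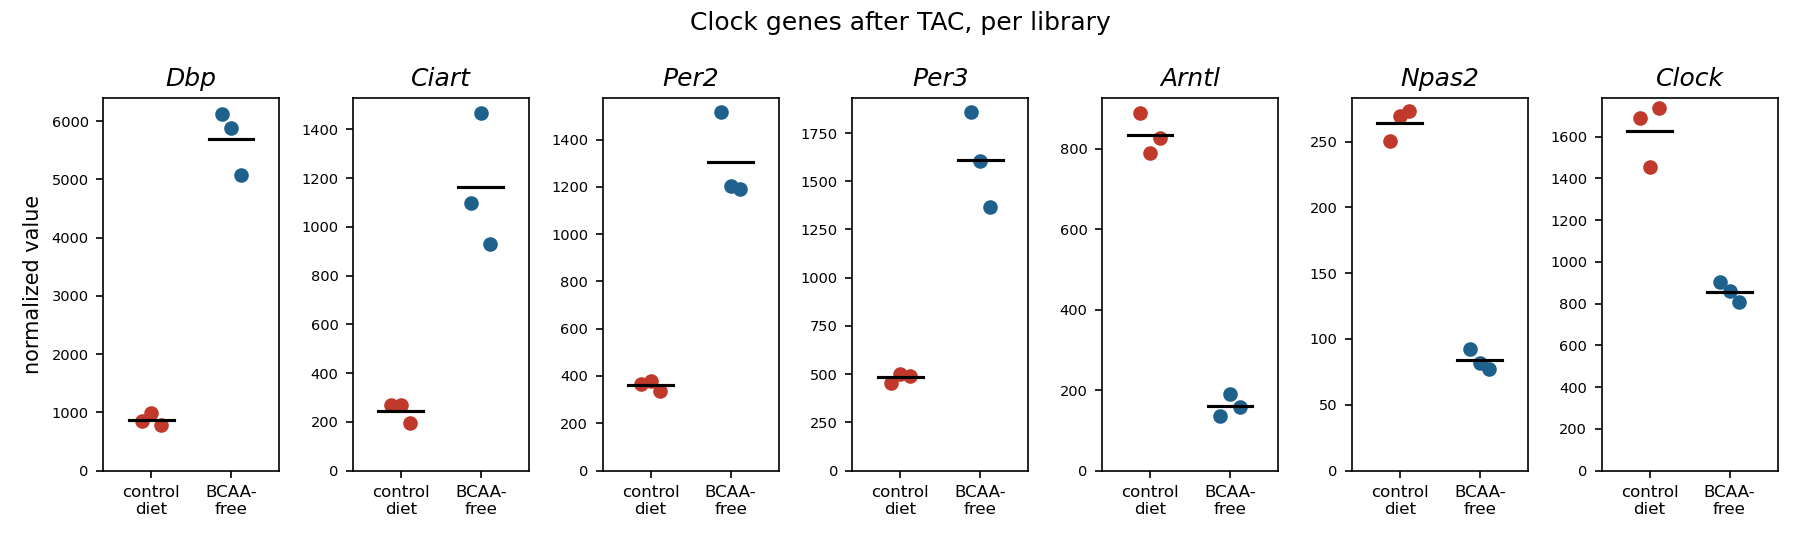
Normalized values (vertical axes, linear from 0) of 7 clock genes in the 3 control diet TAC and 3 BCAA-free TAC libraries, with 1 point per library and a black bar at each group's mean. Dbp lies between 779.5 and 989 on the control diet and between 5074 and 6131 on the BCAA-free diet, and Arntl between 789 and 888 and between 136 and 189.

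Matrix, interferon, macrophage and cell cycle genes were lower on the BCAA-free diet after TAC. In the matrix list 20 of 35 fell and none rose (median -1.74, camera adjusted p = 2.80e-12), among them the fibrillin gene Fbn1 (-2.25 ± 0.23), Col15a1 (-2.11 ± 0.25), Sparc (-1.72 ± 0.31) and Mmp14 (-1.28 ± 0.24). In the interferon list 24 of 25 fell (median -1.12, 1.31e-12), for example Rsad2 (-1.59 ± 0.12) and Zbp1 (-2.12 ± 0.24). In the macrophage list 20 of 26 fell and 1 rose (median -0.77, 2.18e-07), for example H2-Aa (-1.70 ± 0.18), the mannose receptor gene Mrc1 (-0.71 ± 0.091) and Csf1r (-0.58 ± 0.078). In the cell cycle list 21 of 26 fell (median -2.08, 1.18e-07), such as Cdk1 (-3.35 ± 0.33) and Ccnb2 (-2.80 ± 0.36), and 2 rose, one of them Cenpf (1.38 ± 0.11). Of the chemokine and cytokine genes 7 of 17 fell (median -0.67, 0.00543), including Ccl9 (-0.67 ± 0.12) and Cxcl16 (-1.13 ± 0.26). Of the fibroblast markers 8 of 14 fell and 1 rose (median -0.41, 0.0171), such as Pdgfra (-0.71 ± 0.068) and Lum (-1.19 ± 0.21). In the hypertrophy list 8 of 15 fell and 1 rose (median -0.92, 2.65e-04), with Acta1 (-2.60 ± 0.22, adjusted p = 5.93e-04), Rcan1 (-1.55 ± 0.22), Nppb (-1.50 ± 0.23) and Cyr61 (-1.32 ± 0.18) lower. With an estimated correlation all of these calls were lost (adjusted p = 0.691 for each). Among genes with a mean value of at least 100 the cell cycle median was -0.53 (adjusted p = 0.258) and the chemokine median -0.43 (adjusted p = 0.102). Endothelial (-0.098, 0.477) and smooth muscle markers (-0.10, 0.536) did not pass.

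Genes of the respiratory chain, fatty acid oxidation and BCAA catabolism were higher on the BCAA-free diet after TAC. Glycolysis (0.16, camera adjusted p = 0.115), mitochondrially encoded (0.20, 0.275) and ketone body genes (0.15, 0.477) did not pass. Neither did sterol and fatty acid synthesis genes (-0.18, 0.29), with 3 up and 6 down. In the respiratory chain list 34 of 40 rose and none fell (median 0.47, camera adjusted p = 2.77e-12), for example Idh2 (0.86 ± 0.12), Cox6a2 (0.83 ± 0.13), Ndufv1 (0.79 ± 0.12) and Atp5j (0.73 ± 0.12). Fatty acid oxidation had 22 of 32 up and 1 down (median 0.46, 1.87e-06), with the fatty acid transporter gene Slc27a1 (1.34 ± 0.13), Mlycd (0.95 ± 0.12), Etfb (0.85 ± 0.16) and Esrra (0.56 ± 0.10). In BCAA catabolism 17 of 27 rose and 1 fell (median 0.45, 5.12e-07). The genes fixed in advance for this pathway all rose. The mitochondrial aminotransferase Bcat2 (chromosome 7, 45570153 to 45589711) rose by 0.64 ± 0.077, adjusted p = 0.00115, and the dehydrogenase subunits Bckdha (0.75 ± 0.14, adjusted p = 0.00502) and Bckdhb (0.72 ± 0.16, adjusted p = 0.0108) followed. The rest were the inhibitory kinase Bckdk (0.46 ± 0.09, adjusted p = 0.00612), the activating phosphatase Ppm1k (0.79 ± 0.14, adjusted p = 0.00438) and the transcription factor Klf15 (0.94 ± 0.21, adjusted p = 0.0135). Asns fell (-0.82 ± 0.25, adjusted p = 0.0332), a call lost in some settings (adjusted p up to 0.0879), among them without control diet TAC replicates 1 and 3 and BCAA-free TAC replicates 1 and 2. The amino acid response list as a whole had 9 of 41 up and 8 down and did not pass (median -0.11, camera adjusted p = 0.802), with Stc2 up (0.56 ± 0.12) and Aldh18a1 down (-0.73 ± 0.16). Ribosomal protein genes rose with 16 of 35 members (0.24, 5.12e-07), and atrial and conduction genes with 5 of 10 (0.65, 0.00968), including Tbx5 (1.04 ± 0.19). Calcium handling genes (0.31, 0.043) had 9 up, such as Kcnh2 (1.31 ± 0.17), and 3 down, such as Slc8a1 (-0.92 ± 0.12), and adipocyte markers (1.23, 0.042) 2 up, one of them Lipe (0.78 ± 0.10). All of these calls were lost with an estimated correlation (adjusted p = 0.691 for each). The calcium handling median was 0.18, 0.25 and 0.33, short of the threshold, without control diet TAC replicate 2 and BCAA-free TAC replicates 2 and 3, and 0.31 (adjusted p = 0.09) among genes with a mean value of at least 100. Also short of it, the adipocyte median was 0.59, 0.88 and 1.01 without control diet TAC replicate 3 and BCAA-free TAC replicates 2 and 3. The adipocyte call was also lost with the GC content and length trends removed (1.14, adjusted p = 0.197) and among genes with a mean value of at least 100 (1.23, adjusted p = 0.145).

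In all, 5435 of 15872 genes differed between the diets after TAC by limma (34.2%), 2618 up and 2817 down, of which 344 and 696 by at least 1 on the log2 scale. Of the 5435, 5404 separated the 3 libraries of one diet from the 3 of the other, against 50.8% of all tested genes and 10% by chance. The authors' deposited test called 2646 up and 2940 down, including 5213 of the 5435. The count was 3500, 3580 and 3368 without BCAA-free TAC replicates 1, 2 and 3. Median transcript GC content was 53.5% for genes that rose and 46.9% for genes that fell. With the GC content and length trends of each library removed 2769 genes were up and 1934 down, with 3721 of the 5435 among them. Scaling to library totals alone gave 1461 up and 3798 down, with the median of all genes at -0.13; directions in this comparison are relative to that median. Across 15138 genes the diet effects after sham and after TAC had a Pearson correlation of 0.40 and a Spearman correlation of 0.27, where genes are not independent replicates. Of the genes called in both comparisons, 30 rose in both (6.52 would by chance; Fisher's exact p = 1.09e-16), 39 fell in both (10.1; 3.83e-17) and 0 moved in opposite directions. Fisher's test treats genes as independent, which they are not, so its p-values do not measure the spread between samples.

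Whether the TAC response itself differed between the diets was tested as an interaction over all 12 libraries, on the joined TAC tables, which were normalized separately; a scale that is common to a table cancels in this contrast. Positive values mean a more positive TAC change on the BCAA-free diet, which for a gene that TAC lowers is a smaller fall. Cebpb had the largest interaction of the 10 genes with the smallest p (2.20 ± 0.26, adjusted p = 0.00478): its TAC response was -0.58 ± 0.21 on the control diet and 1.62 ± 0.11 on the BCAA-free diet. The others with a more positive response on the BCAA-free diet were the growth factor gene Vegfb (1.03 ± 0.14), Aes (1.11 ± 0.15), Rap1gap (1.25 ± 0.17), Fam131a (1.00 ± 0.14) and Rnf187 (0.89 ± 0.12). Those with a more negative one were Prrg3 (-1.30 ± 0.17), Creb5 (-1.24 ± 0.17), Plekhg1 (-1.16 ± 0.14) and Fam102b (-1.11 ± 0.14). All 10 had an adjusted p of 0.00478. Fbn1 rose after TAC by 1.45 ± 0.22 on the control diet, with -0.034 ± 0.094 on the BCAA-free diet, an interaction of -1.48 ± 0.26, adjusted p = 0.0121. Ifit2 showed 1.03 ± 0.15 on the control diet and 0.026 ± 0.12 on the BCAA-free diet (-1.0 ± 0.20, adjusted p = 0.0154). Ndufb10 showed -0.66 ± 0.17 on the control diet and 0.26 ± 0.07 on the BCAA-free diet (0.92 ± 0.19, adjusted p = 0.0177).

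By list, the extracellular matrix response to TAC was smaller on the BCAA-free diet, with a median interaction of -1.47 and 4 of 35 genes passing, 27 when adjusted over the list alone (camera adjusted p = 1.53e-14). The hypertrophy (-0.92, 8.93e-04), interferon (-0.71, 5.60e-07), smooth muscle (-0.37, 0.0169) and cell cycle lists (-1.09, 0.0094) were lower too. Called members were Xirp2 (-1.72 ± 0.38), Rsad2 (-1.14 ± 0.23), Rgs5 (-0.69 ± 0.15) and Kif11 (-1.88 ± 0.41). The respiratory chain list was higher, with 25 of 40 members called and a median of 0.65 (4.43e-19). So were fatty acid oxidation (12 of 32; 0.60, 6.74e-10), BCAA catabolism (7 of 27; 0.45, 9.88e-07), glycolysis (5 of 25; 0.34, 6.37e-05), sarcomere (2 of 18; 0.27, 0.0243) and ribosomal protein genes (2 of 35; 0.39, 3.56e-06). Examples were Mlycd (1.05 ± 0.16), Esrra (0.73 ± 0.14), Bcat2 (0.55 ± 0.13), Mccc2 (0.67 ± 0.15), Eno3 (0.75 ± 0.16) and Tnni3 (0.99 ± 0.22). With an estimated correlation all 11 calls were lost (adjusted p = 0.675 to 0.794), and by fry the sarcomere list alone passed (adjusted p = 0.0357). The cell cycle median was -0.62 without control diet sham replicate 2 and -0.70 without control diet TAC replicate 2 (adjusted p = 0.102 and 0.0975). That call was also lost with library totals alone (-1.26, adjusted p = 0.0613) and among genes with a mean value of at least 100 (-0.14, adjusted p = 0.756). Macrophage markers did not pass (-0.29, 0.0964).

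**Figure D4:**
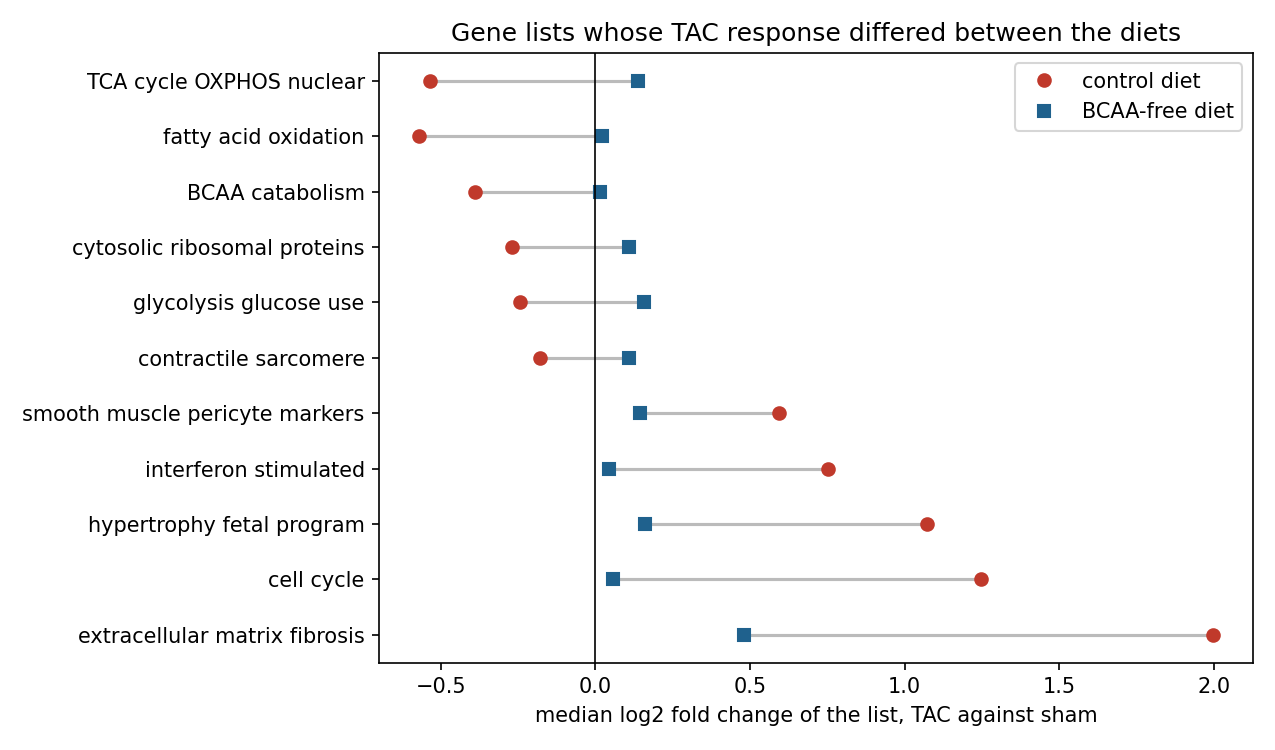
Median log2 fold change of TAC against sham (horizontal axis) on the control diet (circles) and the BCAA-free diet (squares) for the 11 gene lists that passed the interaction test with the preset correlation, 1 line per list. The extracellular matrix list lies at 2.00 on the control diet and 0.48 on the BCAA-free diet, and the respiratory chain list at -0.54 and 0.14.

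In total 1314 of 15195 genes passed the interaction test by limma, 747 positive and 567 negative, 115 and 133 of them by at least 1 on the log2 scale. The size of the response was measured on genes called for the average TAC effect over both diets. The 826 genes that rose on average had a median TAC log2 fold change of 0.74 on the control diet and 0.31 on the BCAA-free diet. Of these, 86% responded less on the BCAA-free diet (median interaction -0.47; camera p = 1.82e-18; p = 0.164 with an estimated correlation). The 529 genes that fell on average had medians of -0.50 and -0.31 (median interaction 0.23; 69% smaller; camera p = 7.18e-08; p = 0.348 with an estimated correlation). Values spread more on the control diet (median SE over all genes 0.16 against 0.12 on the BCAA-free diet), so noise can favour a smaller response among genes chosen this way. Genes were therefore also chosen on an average that weights each diet by its precision per gene. The 450 that rose then had a median interaction of -0.29 (72.7% smaller; camera p = 1.68e-04; p = 0.491 with an estimated correlation). The 233 that fell had -0.055 (44.2% smaller) and did not pass limma's camera at a p of 0.725. With the GC content and length trends removed the genes that fell, then 55, had 0.35 (81.8% smaller) and passed at a p of 1.67e-07, so the result for lowered genes depended on the setting. Across 15088 genes the TAC responses on the diets had a Pearson correlation of 0.16 and a Spearman correlation of 0.04, where genes are not independent replicates. On both diets 39 genes rose (15.2 would by chance; Fisher's exact p = 6.51e-08), 11 fell (5.04; 0.0184) and 19 moved in opposite directions. Here too Fisher's test treats genes as independent, so its p-values do not measure the spread between samples.

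The interaction count depended on single libraries and on base composition. It was 634 and 635 without control diet TAC replicates 2 and 3, 297 and 278 without BCAA-free sham replicates 1 and 2, and 438, 691 and 216 without BCAA-free TAC replicates 1, 2 and 3. The interaction correlated with GC content across genes (Spearman 0.30) and with transcript length (-0.37), and with these trends removed 644 genes passed, 503 positive and 141 negative. DESeq2 called 2188, and library totals alone gave 386 positive and 1462 negative, with the median of all genes at -0.20. Of the 49 named genes that passed, 11 did so in every setting: Plekhg1, Cebpb, Fam102b, Prrg3, Vegfb, Aes, Creb5, Rap1gap, Fam131a, Mlycd and Fbn1. The settings include an absolute log2 fold change of at least 1, which genes with smaller interactions fail by construction. Without that cut and the fits that leave out 1 library, 29 of the 49 kept their call. In the TAC comparison on the control diet 0 of 48 called named genes passed in every setting. That was fixed in advance, because 0 genes were called by limma without control diet TAC replicate 3. The counts that passed in every setting were 2 of 47 on the BCAA-free diet (Cebpb and Acta1), 3 of 24 for the diet after sham and 37 of 76 for the diet after TAC. Without the size cut and the fits that leave out 1 library, 24 of 48 kept their call for TAC on the control diet. In the same settings it was 2 of 47 for TAC on the BCAA-free diet, 11 of 24 for the diet after sham and 66 of 76 after TAC. No called named gene changed direction in any setting tried.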

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

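The tests of 1 common scaling factor, of the GC content and length trend and of 1 library for the smaller TAC response, and of a clock phase shift were chosen only after the result was seen, and so was the removal of that trend as an alternative. Genes and lists with lower or higher interactions were singled out because they passed the interaction test. Clock genes were singled out from the diet comparison after TAC, and as a list they did not pass that test (median 0.24, camera adjusted p = 0.497). Camera looks for a shift in a single direction, and clock genes moved in opposite directions by arm. Their moves can cancel, so the miss does not show equal TAC responses of the clock. Values are log2 interactions, positive where TAC moved the gene or list more upward on the BCAA-free diet.

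Lower interactions were found for the medians of the matrix (-1.47), cell cycle (-1.09), hypertrophy (-0.92), interferon (-0.71) and smooth muscle lists (-0.37). None of these 5 lists kept its call at an estimated correlation (adjusted p = 0.675 to 0.794), and among genes with a mean value of at least 100 the cell cycle median was -0.14 (adjusted p = 0.756). Among matrix and cell surface genes these were Fbn1 (-1.48), Col14a1 (-1.65), Col8a1 (-2.14) and Mmp14 (-1.11). The hypertrophy members were Xirp2 (-1.72), Enah (-0.92) and Rcan1 (-0.95), and the cell cycle gene Kif11 (-1.88) went the same way, whereas Cenpf (0.86) went up. Interferon members were Rsad2 (-1.14), Ifit2 (-1.0), Ifih1 (-0.96) and Ddx58 (-0.72), and vessel wall members Rgs5 (-0.69) and Mcam (-0.63). Of the genes with the smallest p, Plekhg1 (-1.16), Fam102b (-1.11), Prrg3 (-1.30) and Creb5 (-1.24) were lower, as were the amino acid transporter gene Slc7a5 (-0.92) and the clock gene Npas2 (-1.17).

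Higher interactions were found for the medians of the respiratory chain (0.65), fatty acid oxidation (0.60), BCAA catabolism (0.45), ribosomal protein (0.39), glycolysis (0.34) and sarcomere lists (0.27). At an estimated correlation these 6 calls were lost too (adjusted p = 0.675 to 0.794). Respiratory chain members were Ndufb10 (0.92), Cox6a2 (0.82), Ndufv1 (0.78) and Cyc1 (0.78), and fatty acid oxidation members Mlycd (1.05), Slc27a1 (0.75), Esrra (0.73) and Cpt2 (0.64). BCAA catabolism members were Mcee (0.84), Mccc2 (0.67), Bcat2 (0.55) and Bckdk (0.50). Glycolysis members were Mpc2 (0.93), Ldhb (0.79), Eno3 (0.75) and Pkm (0.59), sarcomere members Tnni3 (0.99) and Myl2 (0.86) and ribosomal protein members Rpl27 (0.73) and Rps2 (0.58). Of the genes with the smallest p, Cebpb (2.20), Rap1gap (1.25), Aes (1.11), Vegfb (1.03), Fam131a (1.00) and Rnf187 (0.89) were higher, as was the serine pathway gene Shmt2 (0.46).

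The TAC response was smaller on the BCAA-free diet for matrix, hypertrophy and interferon genes, calls that were lost with an estimated correlation (adjusted p = 0.675, 0.697 and 0.675). The sets of genes raised by TAC passed camera at the preset correlation only. For them the size of the median interaction argues against 2 explanations, by cut-offs set after the result was seen. These genes were chosen anew in each setting, on an average weighted by precision per gene. The 450 genes of the first fit had a median interaction of -0.29. Without control diet TAC replicate 2, whose Nppa value stood apart, 262 genes had -0.30. With the GC content and length trends removed 107 genes had -0.47. With an estimated correlation none of these sets passed. They are also not the matrix, hypertrophy and interferon lists themselves. For list means a common factor for the whole response stays open. Respiratory chain genes lay 0.27 (SE 0.11) above its prediction, but that list was picked for its interaction. Of 33 lists with adjustment over them 1 departed, sarcomere genes (0.20, SE 0.042), and 0 with the GC content and length trends removed. Called genes argue against a positive common factor for every gene. On both diets 39 rose and 11 fell, but 19 moved in opposite directions, a count not repeated with those trends removed. The smaller response may reflect an effect of the diet on remodelling, or a weaker constriction or fewer infiltrating cells in this group, since no pressure gradient or cell count was analysed here.

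Clock genes differed between the diets after TAC. The arm of Per, Dbp and Nr1d genes and the arm of Arntl, Npas2 and Clock moved apart by 2.88 (SE 0.085), in opposite directions (1.23 and -1.65), but the test was chosen on these genes after they were seen to move apart, so it cannot tell whether the clock phase differed. A trend over GC content and length is argued against, since 100% of the called clock genes, 13 of 13, were called with it removed. After sham surgery the arms differed by 1.55 (SE 0.71) in the same direction, and between TAC and sham they differed by 0.55 (SE 0.18) on the control diet and 1.88 (SE 0.69) on the BCAA-free diet. The cause stays open: the collection time is not in the labels, and feeding times and a direct effect of the diet were not tested.

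Short GC-rich genes had higher interactions and long AT-rich genes lower ones. Removing each library's trend over GC content and length kept 35.2% of the called genes, 463 of 1314. A difference between libraries in the recovery of fragments therefore fits the loss of most of these calls. The median absolute log2 value of the called genes went from 0.72 (median SE 0.17) to 0.55 (0.15). They were chosen by the fit before the removal, so the remaining size does not tell how much is free of the trend. No single library carried the trend, because the lowest rank correlation of the interaction with GC content was 0.27 with each library left out in turn. The trend could instead belong to the biology of the affected genes. All 3 BCAA-free TAC libraries share it (Spearman 0.20, 0.40 and 0.39), and the labels give no batch that would separate handling from group.

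For each of the 4 comparisons of pairs of groups the 6 libraries allow 10 splits, too few for a share under 0.05; only the real split, 1 of 10, gave as many genes, with 622, 977, 95 and 5435 genes for TAC on the control diet, TAC on the BCAA-free diet, the diet after sham and the diet after TAC, against 0 as the highest of the other splits by limma in each. For the interaction count itself chance was not excluded at a share under 0.05: 5 of 100 splits of the libraries into diets, the real one among them, gave at least its 1360 genes on TMM-rescaled values, with 3690 for the highest of the others. The other 4 (2057, 2503, 3690 and 1378) kept the TAC libraries of each diet together and so carry the diet difference after TAC, which points to a structure of the samples; 3 more that did so gave fewer genes than the real one (734, 877 and 1036). Splits that mixed the TAC libraries gave 0 or 1 gene. The split with 3690 genes exchanged the diets of the TAC libraries, so its contrast adds the diet effects after sham and after TAC. Counts from such splits carry a plain diet effect, and they cannot decide whether chance gave the interaction count.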

How the results depend on the processing

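The removal of GC content and length trends, edgeR on recovered reads, limma on 12 libraries and part of the alternatives for the size of the response were chosen only after the data were seen. Counts of called genes are given for TAC on the control diet (622), TAC on the BCAA-free diet (977), the diet after sham (95), the diet after TAC (5435) and the interaction (1314). TMM-rescaled values, no filter and a pseudocount of 10 left all 5 counts within 1.5 times the first value, with at least 598 of the 622 control diet TAC genes kept. Of the 281 values of named genes 0 reversed with a call in the first fit or in the changed setting. Sign changes without a call in either were not counted. In 1048 settings a call was lost and in 4311 it was on the same side of the threshold.

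Library totals alone gave 1416 genes for TAC on the control diet. With the GC content and length trends removed the counts were 1537, 85, 375 and 644 for TAC on the control diet, TAC on the BCAA-free diet, the diet after sham and the interaction. DESeq2 gave 2206, 532 and 2188 for TAC on the control diet, the diet after sham and the interaction, and limma-voom 337 for TAC on the control diet. On all 12 libraries edgeR gave 3046, 62 and 322 for both TAC comparisons and the diet after sham, and limma 2988 and 59 for both TAC comparisons. A mean value of at least 100 gave 52 for the diet after sham. An absolute log2 fold change of at least 1 left 244, 39, 44, 1040 and 248 genes in the 5 comparisons by its construction. For the others the cause was not tested.

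Leaving out 1 library gave 0 to 1061 genes for TAC on the control diet, lowest by limma without control diet TAC replicate 3, where 3372 had an unadjusted p under 0.05, and highest without replicate 1. It gave 48 to 1211 for TAC on the BCAA-free diet, lowest without BCAA-free TAC replicate 3 and highest without BCAA-free sham replicate 3; 6 to 475 for the diet after sham, lowest without BCAA-free sham replicate 2 and highest without control diet sham replicate 3; 3368 to 5271 for the diet after TAC; and 216 to 1733 for the interaction, lowest without BCAA-free TAC replicate 3 and highest without control diet TAC replicate 1. Fewer libraries can lower a count, but all such fits of a comparison had the same number of libraries. The counts therefore differed with the library left out, and the cause was not tested. The median interaction of genes raised by TAC on average stayed negative in each such setting, from -0.63 to -0.35, and that of genes lowered stayed positive, from 0.097 to 0.40. Among genes lowered by at least 1 on average, 15 in number, it was 0.56, short of the threshold at a p of 0.0659 by limma's camera; fewer genes were tested there. Chosen on an average weighted by precision, the lowered genes had a median of -0.055 with a weight per gene, the opposite sign, and 0.058 with 1 weight for all genes, short of the threshold at a p of 0.725 and 0.244 by limma's camera. With the GC content and length trends removed the same choices gave 0.35 and 0.39 and passed. Without control diet TAC replicate 2 they gave -0.07, short of the threshold, and 0.18, which passed. The raised genes had -0.29 and -0.42 and passed. Larger spread on the control diet (median SE 0.16 against 0.12) can produce such a loss, since it enters both the plain average and the interaction.

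Of the list tests, 62 passed camera over the 5 comparisons, 61 to 69 without 1 library, 0 with an estimated correlation and 7 by fry, which tests each list on its own. Lists that passed camera in the first fit or in the changed setting changed direction in 5 settings. Sign changes of lists that passed in neither were not counted. With the GC content and length trends removed the immediate early list had a median of -0.12 for TAC on the BCAA-free diet. It then passed camera (adjusted p = 0.0339), which it did not before the removal. Without BCAA-free sham replicate 3 the unfolded protein response median was 0.0040 in that comparison, against -0.21 at the other end of its range. For the diet after sham, the glucocorticoid median was -0.18 without control diet sham replicate 1 and 0.35 without BCAA-free sham replicate 3. Without control diet sham replicate 3 the ribosomal protein median was 0.074 (lowest -0.25, without replicate 2) and the NRF2 median 0.20 (lowest -0.10, without BCAA-free sham replicate 3). Without that control diet library both lists passed camera (adjusted p = 0.0114 and 0.00174), which neither did with all libraries. The cause was not tested.

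With the replicate number as a replicate block the counts were 822, 1321, 143, 4640 and 1584. Residual correlations of libraries with the same number were -0.0068, -0.085 and -0.13 for TAC on the control diet, -0.13, 0.15 and 0.061 for TAC on the BCAA-free diet, 0.0045, 0.14 and -0.0063 for the diet after sham and 0.027, -0.05 and -0.24 for the diet after TAC. Those with other numbers ranged from -0.27 to 0.38. In no comparison were all 3 over 0.1, so the numbers were not taken to pair the samples. Depth limits genes near the filter most, where BCAA-free sham replicate 2 had 13848953 reads over the genes of its TAC table.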

Other observations

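Tests of gene families by symbol were chosen only after the result was seen; they were run on all families with at least 10 tested members. Genes of the mitochondrial ribosome followed the respiratory chain. The 50 Mrpl genes had a median of -0.37 after TAC on the control diet, with 0 members above 0 (camera adjusted p = 4.40e-11), and 0.17 on the BCAA-free diet, with 45 above 0 (2.56e-06). On the BCAA-free diet they were lower after sham (median -0.21, 0 called up and 0 down) and higher after TAC (median 0.30, 26 called up and 0 down), and the interaction median was 0.54, with 19 called up. The 29 Mrps genes showed -0.37 and 0.16 for TAC on the control and BCAA-free diets and an interaction of 0.52, with 9 called. With the GC content and length trends removed the interaction medians were 0.46 and 0.49. None of these families passed with an estimated correlation (adjusted p = 0.717 for the interaction; for Mrpl, 0.987 for the diet after sham and 0.766 for the diet after TAC).

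The median of the 10 toll-like receptor genes was 0.91 after TAC on the control diet, with 2 called up (camera adjusted p = 4.66e-04; 0.718 with an estimated correlation), and -1.07 for the BCAA-free diet after TAC, with 7 called down (camera adjusted p = 3.28e-04; 0.766 with an estimated correlation). Kinesin genes, many of them part of the mitotic spindle, had a median of -0.55 in the same comparison, with 18 of 35 down and 2 up. Tfrc, the transferrin receptor gene, was lower on the BCAA-free diet in both states, by -1.52 ± 0.15 after sham and -1.58 ± 0.083 after TAC. Gm42418, a gene model named here after its values were seen, had -0.83 ± 0.11 for the diet after sham, with 41162 ± 3469.7 on the control diet and 23086 ± 1612 on the BCAA-free diet. Its share of recovered reads was 0.12% to 0.15% in control diet sham and 0.073% to 0.084% in BCAA-free sham libraries. The labels give no batch, so a difference in handling could not be told apart from the diet.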
